A study of Mus musculus with 2 samples.

How the data were processed

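The series holds 2 samples of mouse cavernous primary pericytes, normal glucose and high glucose, each a pool of RNA from 3 samples and each hybridised to 1 array. The labels give the glucose as 5 and 30 mmol, without stating a volume, and the exposure as 72 h. An osmotic control is not used here. Groups were taken from the labels.

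Per the file headers, the deposited intensity values were made with Feature Extraction 11.5.1.1 from 1-colour Cy3 scans of an Agilent mouse expression design. The submitters' processing notes name Agilent Feature Extraction 9.3.2.1 instead, and the discrepancy stays open. Per the file headers, the processed signal is a linear intensity from which background was subtracted and which was detrended within the array; it was not scaled between arrays. Low values are replaced there by small positive surrogates, so dim signals carry little information on ratios. The 0 or 1 spot flags (well above background, saturated, outlier) also come from that software, per the file headers. The authors' deposited value table holds the same linear processed signal: for 55249 of 55249 probes with 1 spot it matched within a relative tolerance of 0.0001, and for 99.8% of all 55681 probes it matched the mean over spots. Its column medians were 49.6 for normal and 48.9 for high glucose. The files hold no log transformation, and scale, centring and direction follow from this match.

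The log2 of the processed signal was taken for 59305 gene spots, 3671 control spots being left out. Spots of 1 probe were averaged and each array's 75th percentile over probes was subtracted; the percentile over spots was 913 for normal and 869 for high glucose. Probes were named through their RefSeq accessions without versions, matched to the RefSeq gene table of assembly GRCm38.p6. Of 55681 probes, 27509 matched 1 symbol, 28172 none and 0 several. The array design names another assembly, mm9, so no coordinates are printed. Unmatched probes, of which 10959 were measured on both arrays, stay unnamed here and enter no gene count. A gene was represented by its probe with the highest mean level; 20887 genes were named and 14176 (67.9%) were well above background and unsaturated on both arrays. A probe with repeat spots counted as well above background when at least 0.5 of its spots were.

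With 1 array per condition no test across genes was run. Genes were counted at 2-fold, and list medians were placed among 10000 random lists drawn within 20 expression bins, for lists with at least 5 measured members. The 31 lists held 562 distinct genes; 8 were markers of cell types. Named genes were chosen by a rule fixed before the data were examined. It took the 12 highest and 12 lowest ratios with all measured probes of 1 sign, leaving out clone, locus and predicted names and odorant receptors, and the 4 highest bounds in each direction. In each list it took up to 4 members past 2-fold or otherwise the 2 largest, and for a list that stood apart the 3 largest in its direction. It added Txnip, Pdgfrb, Cspg4, Rgs5, Anpep, Kcnj8, Acta2, Gapdh and Actb. 1 member that the rule takes from the lists is not reported here. Other list members are named as examples chosen after their values were seen.

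Spot quality was described by 2 measures chosen after the data were seen. The ratio was recomputed from median pixels minus local background. The shift of dim neighbours was the median log2 ratio of median pixel signals over spots within 2 rows and columns that were not well above background on at least 1 array, less the same median over all such spots, if at least 3 such neighbours existed. A local patch was noted for a probe printed once where the median pixel log2 ratio was below 0.5 of the processed one, or the neighbours were shifted by at least 0.5 in the same direction.

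Counting and list steps were tested on simulated data, a copy of the normal glucose array with noise and 200 genes changed by 1.5 on the log2 scale, over 14527 genes for this comparison. With noise from repeat probes well above background, 198 of 200 changed genes passed 2-fold and 2 unchanged genes did. With noise from all repeat probes, dim ones included, 197 of 200 and 222 unchanged genes did, over 14526 genes. The first noise source was adopted after the result of the second had been seen, since counted genes are well above background. Of 200 unshifted random lists of 20 genes 5 stood apart with the first and 7 with the second noise source. Of 50 lists shifted by 0.2 all 50 did with either. The simulated noise was independent between spots, at the median SD of each signal band. It held no local patches, probe error or differences between pools, so these rates are not error rates of the real counts.

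Alternatives tried were quantile normalization, median centring, cyclic loess, a 75th percentile over detected probes, the deposited value table, no dim filter, only genes brighter than the median gene, flagged spots left out, the median over probes, a smooth position trend removed, 1.5-fold and 3-fold thresholds, unmatched random lists, list means, and a looser detection flag. For genes measured on 1 array only, the counts of 505 and 339 used as floor the lowest mean over the spots of a probe. That mean, 20.5 in normal and 16.4 in high glucose, came on each array from a probe with 2 spots, and lay below every spot well above background. The printed bounds therefore use the lowest such spot, an alternative added after the results were seen; it places Armh1 among the 4 highest bounds in place of Prr30. The mean spot signal is not used here, so normexp with offset 50 was run on median spot and background signals, an alternative added after the files were seen. Counts without local patches and counts backed by a second probe were also added then. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.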

Results

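Gene expression was measured in cultured pericytes, the contractile cells that wrap small vessels, isolated from the penile cavernous tissue of C57BL/6 mice. The cells were kept for 72 h in normal glucose, labelled 5 mmol, or in high glucose, labelled 30 mmol. RNA of 3 samples was pooled for each condition and hybridised to 1 Agilent 1-colour array, so the comparison has 1 array per condition and no replicate check. No p-value is given for any gene, and every difference below is between these 2 pools. The normal glucose array had 56.3% of 59305 gene spots well above background and the high glucose array 57.6%, with no saturated spot on either. Both arrays lay on the same slide and were scanned at the same time. The number of arrays limits the precision.

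The question was which transcripts differ between pericytes in high and normal glucose. The 2 pools were close to each other: of 14176 named genes measured on both arrays, 87.7% differed by less than 1.2-fold, and the log2 ratio of high over normal glucose had an SD of 0.24. At least 2-fold differences were seen in 130 genes, or 0.92% of those measured, with 71 higher and 59 lower in high glucose. The clearest was Hmox1, haem oxygenase 1, which breaks down haem. Its processed signal was 11703 in normal and 97417 in high glucose, 8.80-fold higher (log2 ratio 3.14), and its second probe gave a log2 ratio of 2.17. Prmt1, an arginine methyltransferase, was the other gene at least 2-fold different whose second probe differed by at least 1.5-fold in the same direction. Its log2 ratios were 1.00 and 1.09, and it was singled out after its values were seen.

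Error within an array was read from probes printed 10 times. Over 283 such probes well above background, the log2 ratio of a spot had a median SD of 0.046. It was 0.29 below a signal of 128, 0.10 from 128 to 512, 0.044 from 512 to 4096 and 0.032 above 4096. Of the 130 genes at least 2-fold different, 81 had a mean signal below 128 and 4 a signal above 4096. A local patch was noted for 20 of the 130. Across 3632 genes with a second measured probe, the log2 ratios of the 2 probes had a Pearson correlation of 0.21. The count was 20 higher and 18 lower when the background was modelled on the median spot signals and an offset of 50 was added. Such an offset by itself shrinks the ratios of dim genes. Among genes brighter than the median gene the count was 4 higher and 2 lower. Without a filter on dim probes it was 666 higher and 606 lower.

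**Figure D1:**
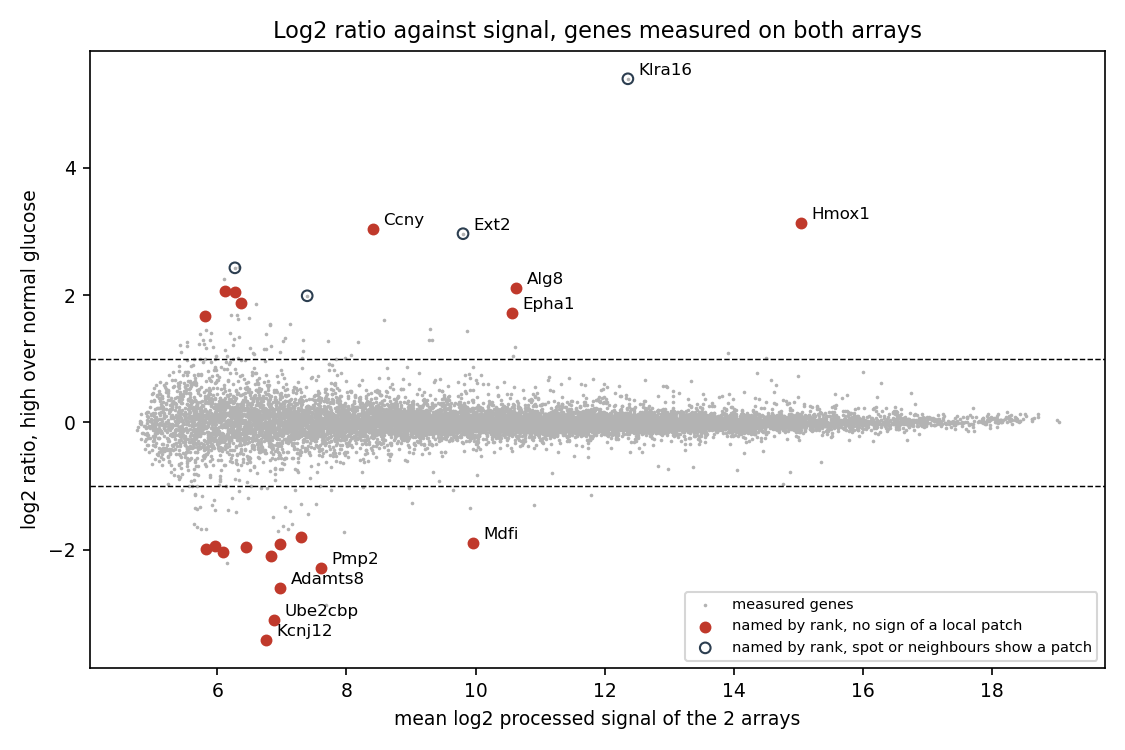
Log2 ratio of high over normal glucose (vertical axis) against the mean log2 processed signal of both arrays (horizontal axis) for 14176 genes; dashed lines mark 2-fold. Red points and open circles are the 12 highest and 12 lowest named genes, the open circles those whose spot or dim neighbours showed a local bright patch; Hmox1 (log2 ratio 3.14) is the brightest of the named genes.

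The 12 genes with the highest ratios whose probes all pointed the same way included Hmox1 and several genes with less secure signals. Ccny (cyclin Y) was 8.23-fold higher, Alg8, a glucosyltransferase of N-glycan assembly, 4.33-fold, and Epha1, an ephrin receptor, 3.29-fold. Each rested on 1 measured probe, with a median pixel ratio close to the processed ratio. Eln (elastin) was 4.19-fold higher, Sycn (syncollin) 4.14-fold, Ranbp3l 3.69-fold and Rab19, a small GTPase, 3.19-fold. The normal glucose signals of these 4 genes were dim, between 32.2 for Rab19 and 44.1 for Ranbp3l. For the remaining 4 the scan showed local disturbance. Klra16, a lectin-like receptor of natural killer cells, was 42.1-fold higher by processed signal, but the median pixel gave a log2 ratio of only 0.71, its dim neighbours were shifted by 1.32 and its second probe gave 0.45. Ext2, a heparan sulphate polymerase, was 7.80-fold higher with a median pixel log2 ratio of 0.41. Nr6a1, a germ cell nuclear receptor, was 5.38-fold and Rab11fip2 3.97-fold higher, with dim neighbours shifted by 0.89 and 0.68.

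The 12 lowest ratios were nearly all of genes with dim signals in high glucose. Mdfi, an inhibitor of myogenic transcription factors, was the brightest of them and was 3.71-fold lower in high glucose, with a signal of 1979 in normal and 505 in high glucose. Kcnj12, an inward rectifier potassium channel, was 10.7-fold lower, Ube2cbp 8.58-fold, Adamts8, a secreted metalloprotease, 6.05-fold, Pmp2, a myelin protein, 4.88-fold and Klk1b3, a kallikrein, 4.28-fold. Speer4d was 4.12-fold lower, Kap 3.95-fold, Zbed3 3.88-fold, Amer3 3.84-fold, Slc8a1, a sodium-calcium exchanger, 3.74-fold and Wdr11 3.50-fold. In high glucose the signals of these 11 genes other than Mdfi lay between 27.8 for Kap and 85.4 for Pmp2, and each rested on 1 measured probe.

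Some genes were well above background on 1 array only, 505 with a higher and 339 with a lower signal in high glucose, which gives a bound on the difference. With the lowest mean over the spots of a probe as floor, 212 and 215 of these had a bound of at least 2-fold. That floor was 20.5 in normal and 16.45 in high glucose. No 2-fold count was made with the higher floor used for the bounds below, so the near balance may depend on the floor. Pate9 was at least 13.99-fold higher, Armh1 at least 7.54-fold, Chst9, a sulphotransferase, at least 7.48-fold, Amigo2, an adhesion protein, at least 7.42-fold and Prr30 at least 7.06-fold. Tcp10b was at least 22.6-fold lower, Pkhd1l1 at least 21.4-fold, Ipcef1 at least 12-fold and Ceacam19 at least 10.7-fold. These bounds set the bright value against the higher of the dim value and the lowest spot signal well above background, 26.9 in normal and 24.0 in high glucose. With this floor the counts of 505 and 339 became 496 and 339. Dim neighbours of the Chst9 spot were shifted in the same direction by 1.43 on the log2 scale, and those of Ipcef1 by -1.05. Spots of probes for external control RNAs reached a signal of 972 in normal and 447 in high glucose. These are maxima over all such spots and lie above the bright signals of all genes named here, so a signal of this size need not reflect expression of the gene. Whether those control spots were dim on the other array is not given, so they were not set against the bounds themselves. With a looser detection rule, positive and significant signal, 756 genes in place of 505 were higher and 627 in place of 339 lower.

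Gene groups fixed before the data were examined moved by small amounts, most far below 2-fold. For each of 31 lists the median log2 ratio was placed among 10000 random lists of the same size and expression level, as a description of these 2 arrays. The median lay outside the central 95% of random lists for 12 lists, 5 on the high and 7 on the low side, where 1.55 would lie outside by chance if genes within a list varied independently, which genes regulated together do not.

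**Figure D2:**
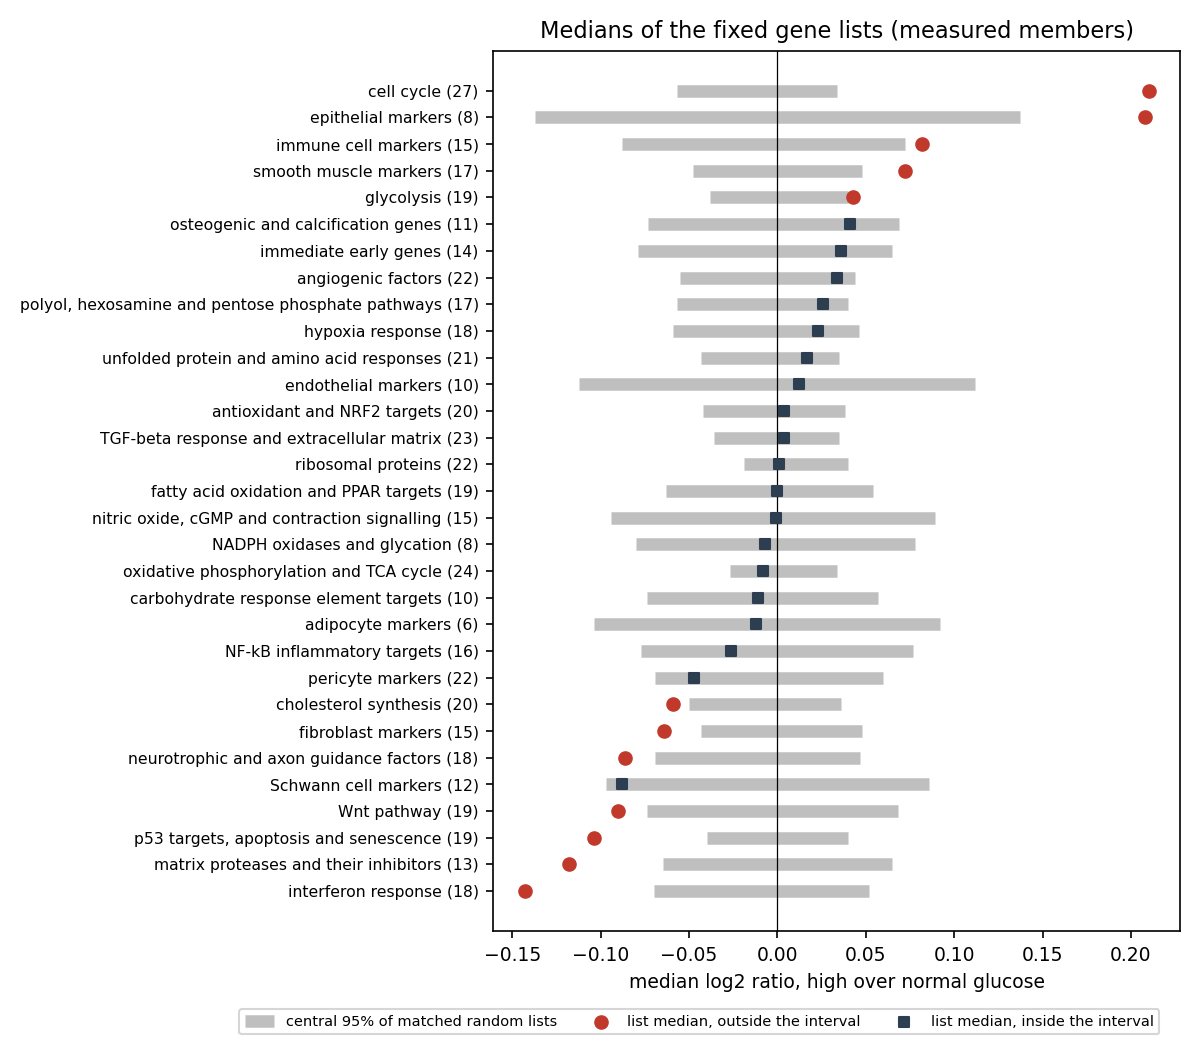
Median log2 ratio of high over normal glucose (horizontal axis) for each of 31 gene lists, with the number of measured members in parentheses; grey bars are the central 95% of 10000 random lists matched on expression. The 12 red circles lie outside their bars, from interferon response at -0.14 to cell cycle at 0.21.

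Cell cycle genes were higher in high glucose. Their median log2 ratio was 0.21, at percentile 100, and 24 of 27 measured members were higher, none of them by 1.5-fold. Nusap1, a spindle protein, was higher by 0.34 on the log2 scale, Kif20a, a mitotic kinesin, by 0.33 and Bub1, a spindle checkpoint kinase, by 0.33. The proliferation marker Mki67 had a log2 ratio of 0.32 and Top2a, a topoisomerase, 0.29, while Mcm2 of the replicative helicase had -0.10; these 3 were chosen after their values were seen. Targets of p53, with genes of apoptosis and senescence, were lower, with a median of -0.10 at percentile 0.00 and 16 of 19 members lower. Gadd45a, a stress sensor, had a log2 ratio of -0.36, Cdkn2a, a cell cycle inhibitor, -0.29, and Cdkn1a (p21) -0.22. The pro-apoptotic gene Bax went the other way at 0.40. The second probe of Cdkn2a gave -0.93 and that of Cdkn1a -0.09.

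Interferon response genes were lower, with a median of -0.14 at percentile 0.00 and 17 of 18 members lower. The 3 other measured probes of 3 members had a median of -0.114, and 1 of them was higher. Rsad2 (viperin) had a log2 ratio of -1.08 and Oasl2, an oligoadenylate synthetase-like protein, -0.24. The signal of Rsad2 was dim, at 121 in normal glucose. Among genes brighter than the median gene the list no longer stood apart, with a median of -0.065 at percentile 5.61. NF-kB inflammatory targets did not stand apart, at -0.026 and percentile 27.7; Cxcl5 had 0.53 and Cxcl10 -0.48, both chemokines. Among the brighter genes their median was 0.08, at percentile 98.8.

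**Figure D3:**
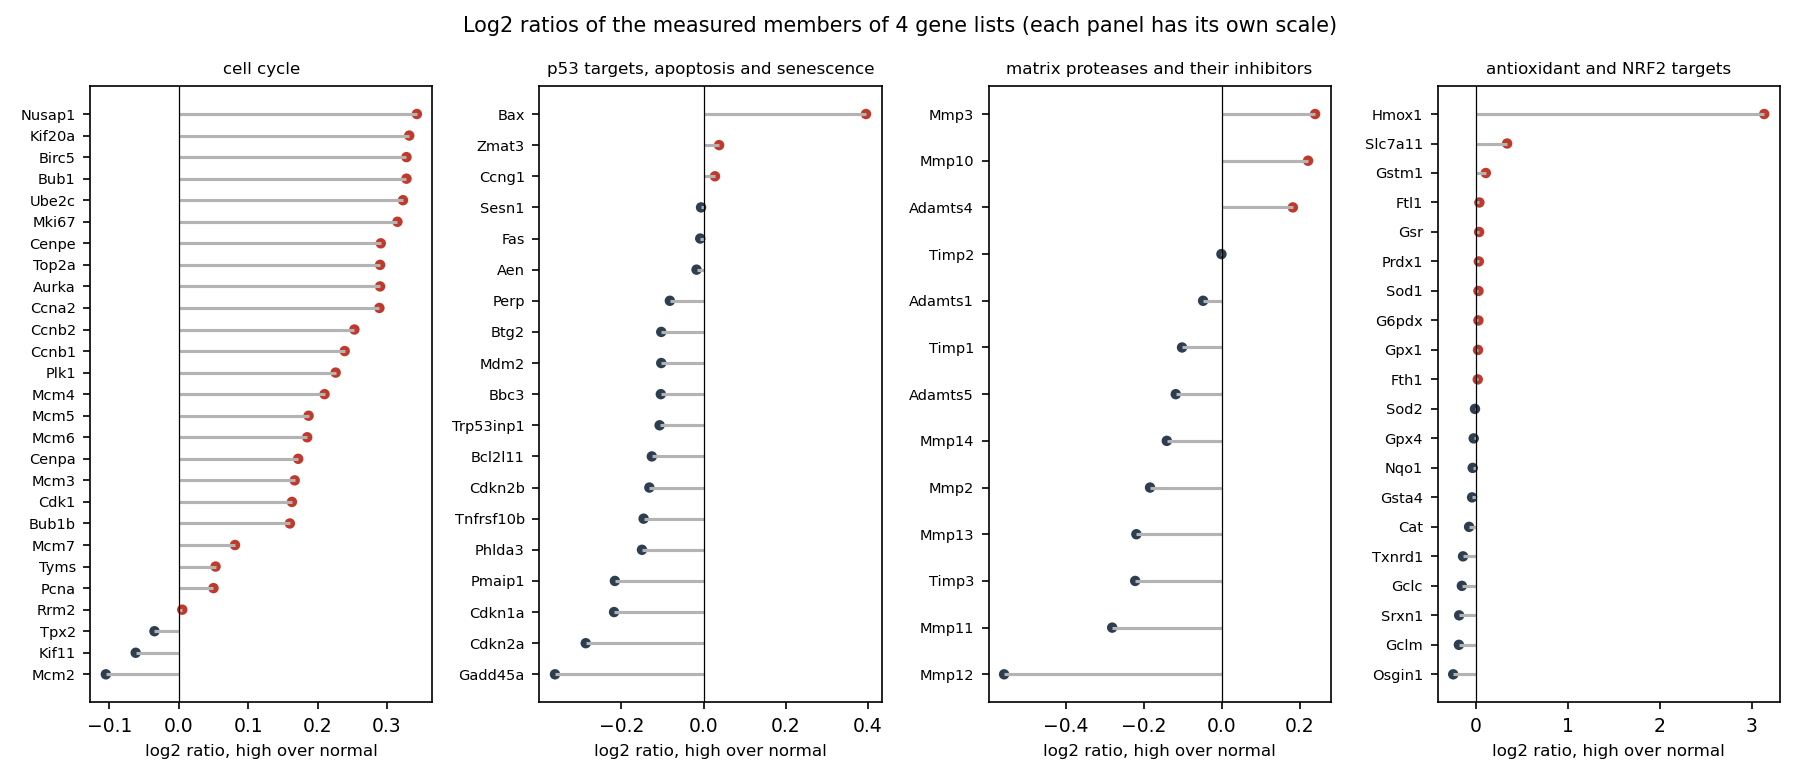
Log2 ratio of high over normal glucose (horizontal axes, a separate scale in each panel) for every measured member of 4 gene lists. In the cell cycle panel 24 of 27 genes lie above 0, in the p53 panel 16 of 19 and in the matrix protease panel 10 of 13 lie below 0, and in the antioxidant panel Hmox1 lies at 3.14 apart from the other members.

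Antioxidant and NRF2 target genes did not move as a group, with a median of 0.004 at percentile 63.9 and 10 of 20 members higher. The mean, 0.134, lay outside the central range at percentile 99.6. Hmox1, with a log2 ratio of 3.14, was the only member past 1.5-fold, and the raised mean came from it. Further members were chosen after their values were seen. Slc7a11, the cystine transporter, had a log2 ratio of 0.34 from a signal of 28.7 in normal glucose. Some classical targets were slightly lower, with Osgin1 at -0.25, Gclm, a subunit of glutathione synthesis, at -0.19, Txnrd1, thioredoxin reductase, at -0.14 and Nqo1, a quinone reductase, at -0.04. Others were slightly higher, with Gstm1 at 0.11, Gsr at 0.03 and Prdx1 at 0.03. NADPH oxidase and glycation genes had a median of -0.007 at percentile 48.3, with Ddost at -0.21 and Msr1, a scavenger receptor, at 0.16. Msr1 was dim, with a signal of 49.3 in normal glucose. Unfolded protein and amino acid response genes had 0.017 at percentile 86.5, with Trib3 at -0.34 and Ddit3 (CHOP) at -0.28. Immediate early genes had 0.036 at percentile 90.3, with Ier3 at 0.39 and Atf3 at -0.22; among the brighter genes they had 0.13 at percentile 99.9.

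Among genes of glucose handling, the largest difference was in Tkt, transketolase of the pentose phosphate pathway, which was 1.66-fold higher. Akr1b3, aldose reductase and first enzyme of the polyol pathway, was 1.31-fold higher, and its second probe gave a log2 ratio of 0.47. The polyol, hexosamine and pentose phosphate list had a median of 0.026 at percentile 93.1, inside the central range. Its mean, 0.074, lay outside at percentile 98.6, and its median was -0.035 with median centring. Txnip, the thioredoxin-interacting protein known to respond to glucose, had a log2 ratio of 0.05, and -0.01 with each array centred on its median. Targets of the carbohydrate response element had a median of -0.011 at percentile 49.3, and Gpd1, a glycerol phosphate dehydrogenase, had -0.23. Glycolysis genes had 0.043 at percentile 98.1, with Slc2a1, the GLUT1 glucose transporter, at 0.33, the lactate transporter Slc16a3 at 0.19 and the pyruvate kinase Pkm at 0.18. This median turned to -0.018 with median centring, at the same percentile. Its call was lost with normexp, with quantile normalization, after removal of a position trend, against unmatched random lists and for the mean.

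Mitochondrial genes showed no shift. Oxidative phosphorylation and TCA cycle genes had a median of -0.008 at percentile 24.8, with the largest difference in Cs, citrate synthase, at -0.12 and Ndufa9 of complex I at -0.10. Their median pixel ratios were smaller, at -0.003 and -0.04. Fatty acid oxidation genes had a median of 0.0 at percentile 61.2. Cpt1b, the muscle carnitine palmitoyltransferase, had 1.40 from a probe with a signal of 33.8 in normal glucose, and its second probe gave -0.05. Cholesterol synthesis genes were lower, with a median of -0.059 at percentile 1.08. Insig1, a sterol-regulated retention protein, had -0.39, Cyp51 -0.12, Nsdhl -0.12 and Fdps, on the other side, 0.16. This call was lost with normexp, the median over probes, the position trend removed, unmatched lists and the mean. Hypoxia response genes had 0.023 at percentile 88.8, with Egln1, an oxygen-sensing hydroxylase, at 0.33 from a dim signal of 107 in normal glucose.

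Among marker genes of cell types, 22 of 24 pericyte markers were measured, with a median of -0.047 at percentile 8.86. Their signals in normal glucose ran from 28.8 for Art3 to 61844 for Cd248. Those of the measured fibroblast markers ran from 51.7 for Clec3b to 428542 for S100a4, so the number of measured markers does not identify the cells. Art3 had a log2 ratio of 1.21 from a probe with a signal of 28.8 in normal glucose. Pdgfrb, the platelet-derived growth factor receptor of pericytes, had 0.14, Cspg4 (NG2) -0.20 and Anpep (CD13) -0.14. Rgs5 had 0.58 from a dim signal of 93.9 in normal glucose, with dim neighbours shifted by 0.35. Kcnj8 was not well above background on either array. Smooth muscle markers were higher, with a median of 0.072 at percentile 99.7 and 14 of 17 members higher; the median was 0.011 with median centring, at the same percentile. Myocd (myocardin), with a signal of 33.0 in normal glucose, had 0.81, the myosin kinase Mylk 0.27 and Myh11 0.22. Acta2, alpha smooth muscle actin, had 0.02, and -0.01 and -0.04 with quantile normalization and median centring. Among the brighter genes the smooth muscle median was 0.028, at percentile 88.0. Fibroblast markers were lower, with a median of -0.064 at percentile 0.33. Clec3b had -0.50, the protease Fap -0.37 and the collagen Col3a1 -0.18. This call was lost among the brighter genes, with the position trend removed and against unmatched lists.

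Of 5 lists of markers of other cells, the epithelial and immune lists were higher and the other 3 lay inside the central range. Endothelial markers, of which 10 of 19 were measured, had a median of 0.012 at percentile 65.8, with Vwf at -0.53 and Flt1 at -0.24. Vwf was dim, with a signal of 74.0 in normal glucose. Schwann cell markers had -0.088 at percentile 3.82, and stood apart with normexp, against unmatched lists and for the mean. Mal had -0.91 and Cdh19 -0.75, from dim signals of 114 and 89.2 in normal glucose. Adipocyte markers had -0.012 at percentile 47.3, with Lpl at -0.27 and Fabp4 at 0.26. Immune cell markers were higher, with a median of 0.082 at percentile 98.5, or 0.021 with median centring. Cd14 had 0.27, Fcer1g 0.23 and lysozyme Lyz2 0.22, while Cd74, the invariant chain, had -1.60 with a median pixel log2 ratio of -0.58. The mean of the immune list was -0.004, so median and mean differed in sign, and the call was also lost with normexp and with the median over probes. Epithelial markers had 0.21 at percentile 99.4 over 8 of 13 members. The keratins Krt14 and Krt5 had 0.41 and 0.22 from dim signals of 29.8 and 45.8 in normal glucose. The splicing factor Esrp1, with a signal of 114 in normal glucose, had 0.32, with a median pixel log2 ratio of 0.12. With no filter on dim probes the epithelial median was -0.063, and the call was lost with normexp and for the mean.

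Matrix and signalling genes were mixed. TGF-beta response and matrix genes had a median of 0.004 at percentile 63.4, and Eln was the only member past 2-fold. Matrix proteases and their inhibitors were lower, with a median of -0.12 at percentile 0.02 and 10 of 13 members lower. Mmp12 had -0.56 from a dim signal of 57.5 in normal glucose, Mmp11 -0.28 and the inhibitor Timp3 -0.22. The mean of the list, -0.095, lay at percentile 3.21, inside the central range. Angiogenic factors had 0.034 at percentile 94.5, with Angpt1, the ligand of the Tie2 receptor, at 0.61 and Ptn (pleiotrophin) at -0.47. With the median over probes the angiogenic list stood at 0.058, percentile 99.2. Neurotrophic and axon guidance factors were lower, with -0.086 at percentile 0.61 and 15 of 18 members lower. Slit3 and the glial factor Gdnf had -0.21 each and Ntf5 0.28, and the second probe of Ptn gave -0.09. The mean of this list, -0.088, lay at percentile 3.82.

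Wnt pathway genes were lower, with -0.090 at percentile 0.94 and 13 of 19 members lower. Wif1, a secreted Wnt inhibitor, had -0.68, the transcription factor Lef1 -0.54 and Nkd1 -0.35, while Frzb had 0.59 beside dim neighbours shifted by 0.51. Wif1 and Nkd1 were dim, with signals of 67.4 and 81.1 in normal glucose. The Wnt call was lost among the brighter genes, with the median over probes and for the mean. Nitric oxide, cGMP and contraction genes had a median of -0.001 at percentile 54.3, with the phosphodiesterase Pde3a at 0.65 and Gucy1a1, a subunit of the nitric oxide receptor, at -0.30, both from dim probes. Osteogenic and calcification genes had 0.041 at percentile 90.1, with Omd at 0.30 and Bmp4 at -0.28, and 0.13 at percentile 99.9 with the median over probes. Ribosomal protein genes had 0.001 at percentile 31.2, with Rpl5 at 0.43 and Rpl19 at 0.13. Gapdh had a log2 ratio of 0.00 and Actb 0.05. Median and mean also differed in sign for pericyte, endothelial, carbohydrate response, unfolded protein and nitric oxide lists, none of which stood apart.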

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

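Of the tests in this part, the one on control spots was chosen after the spot values were seen. The array carries 2772 spots of probes for external control RNAs, which enter no gene count or list of the report and whose median signal was 6.26 on the normal and 5.50 on the high glucose array, at background level. Of these spots 162 were well above background in normal and 182 in high glucose; a false rate of the flag was not measured separately. On both arrays 89 were so, and 51.7% of the calls on either array came from 5 of the 96 probes. The pattern bears on genes above background on 1 array only. Sporadic signal on spots without target may account for part or most of those bounds. The gene side was limited to probes printed once and covered only a part of all dim gene spots. Of 8446 such spots dim in normal glucose, 2.32% (Wilson 95% interval 2.02 to 2.66) reached a 2-fold bound in high glucose. The share was 1.90% (1.47 to 2.46) of 2949 dim control spots, taken from the external control spots and 350 spots of 10 spike-in probes. In the other direction the shares were 2.01% (1.73 to 2.34) of 8210 gene spots and 1.40% (1.04 to 1.90) of 2921 control spots. The gene spots had the higher share in both directions, and the intervals overlapped. The intervals treat spots as independent, though the control spots are repeat prints of 96 and 10 probes. Overlap of intervals is also not a test of a difference. Bounds from expression and from sporadic signal therefore cannot be told apart here, and whether glucose acts on these genes was not tested beyond that.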

How the results depend on the processing

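The normexp background, the floor from the lowest single spot, the counts without patches and the counts backed by a second probe were chosen after the data were seen; all other settings were fixed before. Scaling on spike-in controls was not run because the median of their spots lies at background, and normexp on mean signals was not run as planned. Of 281 values of the 28 named genes past 2-fold, all 281 kept their direction and 267 stayed past 2-fold. These genes were taken for their large ratios, which could hardly turn under settings that moved most ratios little. They include Klra16 and Ext2, whose spots showed a local patch. The tally therefore does not show that the differences are free of spot error. Cell cycle (0.15 to 0.23) and p53 targets (-0.16 to -0.09) stood apart under every setting run. Higher and lower counts were 20 and 18 with normexp, 666 and 606 with no filter on dim probes, 4 and 2 among genes brighter than the median gene, 229 and 169 at 1.5-fold, 20 and 23 at 3-fold, and 2 and 0 when a second probe had to differ by 1.5-fold; the last is limited by the 14 genes that have a second probe. Without local patches they were 59 and 51. The SD of log2 ratios was 0.17 with normexp, 0.62 unfiltered and 0.14 among the brighter genes. Of genes measured on 1 array only, 756 were higher and 627 lower with the looser detection flag, and 496 and 339 with the floor from the lowest single spot. For list medians the cause of each change was not tested. With normexp Schwann markers (-0.097) came to stand apart, and immune (0.016), epithelial (0.091), glycolysis (0.017) and cholesterol (-0.045) lists no longer did. Glycolysis was 0.028 with quantile normalization. Median centring subtracts 1 constant from every ratio, so it moves every list median down alike and leaves the percentiles: glycolysis was -0.018, smooth muscle 0.011, immune 0.021, epithelial 0.148 and cell cycle 0.149. Unfiltered, the epithelial median was -0.063. Among the brighter genes smooth muscle (0.028), fibroblast (-0.032), interferon (-0.065) and Wnt (-0.037) lists no longer stood apart, and NF-kB (0.080) and immediate early (0.127) lists did. With the median over probes immune (0.066), cholesterol (-0.049) and Wnt (-0.039) lists no longer stood apart, and angiogenic (0.058) and osteogenic (0.127) lists did. With the position trend removed fibroblast (-0.037), glycolysis (0.019) and cholesterol (-0.051) lists no longer stood apart. Against unmatched random lists fibroblast (-0.064), glycolysis (0.043) and cholesterol (-0.059) lists no longer did and Schwann markers (-0.088) did. For the mean, Schwann (-0.194), polyol (0.074) and NRF2 (0.134) lists stood apart, the immune mean was -0.004, and epithelial (0.171), glycolysis (0.046), cholesterol (-0.048), protease (-0.095), neurotrophic (-0.088) and Wnt (-0.084) lists no longer did. No paired analysis was possible because each condition has 1 array.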

Other observations

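The test of second probes on the genes at least 2-fold different, the spot measures behind the local patches and the osmotic gene sets were chosen only after the values were seen, as were the genes named in this paragraph. Among genes with a mean signal above 512 and no local patch, several not described above differed by at least 2-fold. Il11, an interleukin of the IL-6 family, was 2.46-fold higher in high glucose, Tifa, an adaptor of NF-kB signalling, 2.46-fold, Slco4a1, an organic anion transporter, 2.70-fold and Lamtor2, a lysosomal scaffold of mTORC1, 2.13-fold. Hebp1, a haem-binding protein, was 2.20-fold lower, with a signal of 5420 in normal and 2336 in high glucose, in the same pools in which Hmox1 was higher. Ass1, argininosuccinate synthase, was 1.55-fold lower, and its 2 probes gave log2 ratios of -0.63 and -0.74. Each of these except Ass1 rests on 1 measured probe. So do Taf15, 2.54-fold lower, Prr7, 2.465-fold, Plcl2, 2.41-fold, and Kifc1, a mitotic kinesin, 2.08-fold lower, as well as Tnpo2, 2.28-fold higher. Zfp955b and Trim12c were 2.05-fold and 2.77-fold higher, but their second probes gave log2 ratios of -0.02 and -0.21.

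Genes at least 2-fold different are the first pattern to weigh. Of the 130 genes, 13.08% (Wilson 95% interval 8.33 to 19.9) had dim neighbours shifted in the same direction, against 0.52% of level-matched genes, so local bright patches likely account for some of them; 110 genes showed neither sign of a patch. Of 14 of these genes with a second measured probe, 2 had it at least 1.5-fold different in the same direction, 14.3% (4.01 to 39.9), which is consistent with error of single probes, although a second probe can also read another transcript. A response to glucose stays open for every gene, Hmox1 and Prmt1 being the 2 with a second probe behind them.

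The cell cycle shift is the second pattern. An intensity trend was argued against by cyclic loess, after which the median log2 ratio was 0.22, and a position trend by the smooth surface, after which it was 0.211. The 8 other probes of 6 members had a median of 0.279, all 8 higher, at percentile 99.95 of matched probe sets, which argues against error of single probes. A further 52 measured cell cycle genes, listed before their ratios were seen, had a median of 0.183 at percentile 100, with 45 higher. Kifc1, a mitotic kinesin in neither list, went the other way, with a log2 ratio of -1.06 from 1 measured probe. With 1 array per condition, a difference in growth or density between the pools and an effect of glucose cannot be told apart.

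A hypothesis drawn from the values is that high glucose acts through osmolarity. Genes known to respond to hypertonic medium and noticed among the higher ones were Slc5a3 and Slc6a12, which import the osmolytes inositol and betaine (log2 ratios 0.53 and 0.60), Akr1b3, which makes sorbitol (0.39), the water channels Aqp1 and Aqp5 (0.60 and 0.78), Hspa4l (0.46), Hspa1a (0.42), Fxyd2 (0.52) and Ranbp3l (1.88). The position trend fitted over spots well above background spanned 0.127 in total, and their median was 0.537 with it removed, which argues against a smooth position trend as the whole cause. The test on 7 measured genes not looked at before, among them Nfat5, Sgk1 and Slc6a6, gave a median of 0.071 at percentile 97.1, just inside the central 95%, with 6 of 7 higher. By the criterion written before the test this does not decide the question, and the first set was picked because it was higher, so osmolarity may or may not contribute.

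The further 28 interferon response genes had a median of -0.060 at percentile 1.01, with 23 lower. The unnamed probes measured on both arrays numbered 10959, of which 153 were at least 2-fold higher and 108 lower.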
